A study of Mus musculus with 23 samples.

How the data were processed

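RNA from whole livers of 23 mice was profiled as polyA RNA with 3' end counting. Per the labels' protocols, livers were homogenised and RNA was isolated on columns with DNase treatment. A sequencing service then reverse-transcribed the mRNA, tagmented, indexed and amplified the cDNA and sequenced it on an Illumina instrument. The mice were of the CYP2E1-KO line 129/Sv-Cyp2e1tm1Gonz/J (KO) or of the line 129S1/SvImJ (WT). Groups and replicate numbers were taken from the sample titles, giving 5 Female WT, 6 Female KO, 6 Male WT and 6 Male KO libraries. The labels call them biological replicates. They give the age as 12 to 13 weeks in the growth protocol and as 16 weeks in another field, and which holds is not known here.

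The deposited table holds an estimated count and a CPM value for each of 65535 genes in each library. Per the submitters' processing notes, the tools were FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32, featureCounts and Subread 2.1.1, with the genome build mm39. The notes used here give neither their order nor their settings. The deposited counts are expected counts that need not be whole, and between 33.7% and 55.0% of a library's counts lie in genes with a fractional count, so reads were divided between genes. They were rounded to whole numbers for all count tests. The deposited CPM values are relative to library totals that exceed the sums of the table by 0.575% to 1.14%. The number of genes equals the number of lines that an xls sheet holds under its header, so genes beyond that limit are probably missing and are not analysed here. No gene name is given for 11373 of the gene IDs, and 32853 genes had a count in any library. The table held 0 columns that belong to no sample.

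Chromosomes were taken by gene ID from the GENCODE mouse release M21 annotation, which uses GRCm38 and not mm39. A position was found for 51487 IDs (78.6%). Positions served only to find chromosomes and neighbours, and no coordinates are given because the builds differ.

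Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default filterByExpr filter, which left 11370 genes. All 23 libraries of the 4 groups entered 1 fit, so that they share an estimate of the spread. The 5 contrasts were KO against WT in females, KO against WT in males, the sex by genotype interaction, and male against female in WT and in KO. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Adjusted p-values of genes are from this edgeR test unless another tool is named. Standard errors were derived from the fold change and the F statistic. The default dispersion estimate took the place of a robust one after results had been seen, and the counts of called genes in the genotype contrasts were the same with either. Group levels are means of deposited CPM values ± SD.

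Before the data were examined, the design, the gene lists, the rule for named genes and most other settings listed below were fixed. The rule names Cyp2e1, then up to 8 genes in each direction with the largest fold change. Such genes are called, reach a mean of 5 CPM in the higher group, have libraries of the groups that do not overlap, and carry a symbol that is not a predicted model. For the sex contrasts it takes 5 genes in each direction and the sex chromosome genes, and for each gene list up to 4 called members. List members that were not called may be named with their values. Those named in the list paragraphs were chosen after their values were seen. Other genes named outside that rule were also chosen after their values were seen, and the text says so. The results of 1 called gene are not reported here, and it was left out when single libraries were compared with their group. Of 39 gene lists, 35 had at least 3 tested members. The untested ones were the markers of T and NK cells, of B and plasma cells, of neutrophils and of exocrine pancreas. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment was over the 35 lists of a contrast.

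The fit was tested on simulated data with 200 changed genes of 11370. Counts were drawn independently from each gene's mean over all libraries. The simulation had no sex difference, no correlation between genes and no outlying libraries, so its shares may not hold for the real contrasts. For females, 21% of genes changed by 1.5-fold, 76.5% of those changed by 2-fold and 95% of those changed by 3-fold were recovered. For males the shares were 25%, 78.5% and 97%. False calls made up 10.6%, 1.9% and 5.5% of the calls in the female simulations and 3.8%, 3.1% and 6.3% in the male ones.

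No libraries were found to be copies: over 55 pairs of libraries of a group, chi-square per degree of freedom was between 3.05 and 37.5. The alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, and median-of-ratios and upper-quartile scaling. Others had no filter or a filter of 1 CPM in 5 libraries, which kept 13519 genes, more than the main filter. Further alternatives were a test against a log2 fold change of 0.5, library sizes without the 20 most abundant genes, only the groups compared in the fit, a replicate block, robust dispersion, the library totals implied by the CPM columns, and leaving out each library in turn. Plain voom, robust dispersion, the implied totals, the list tests with 1 library left out or other scaling, the overlap by other tools and the genotype difference averaged over the sexes were added after the data were seen. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. Counts come from PCR-amplified reads and no molecular identifiers are described in the sources used here, so counting intervals and floors of 3 counts cover counting error only.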

Results

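Liver gene expression was compared between CYP2E1-KO mice, whose gene for the cytochrome P450 enzyme CYP2E1 is disrupted, and WT mice of another 129 line, in both sexes. CYP2E1 oxidises ethanol, acetone and several drugs in hepatocytes. There were 5 Female WT, 6 Female KO, 6 Male WT and 6 Male KO libraries. Each genotype is also a separate line, so a difference between genotypes can come from the disrupted gene or from any other difference between the lines. Library totals ranged from 1538889 counts in Male KO replicate 3 to 9874733 in Male WT replicate 3, with a median of 4658677. The group means were 5349643 ± 909395 (SD, n = 5) in Female WT, 4634529 ± 360708 (SD, n = 6) in Female KO, 5812956 ± 2083042 (SD, n = 6) in Male WT and 4067528 ± 1481176 (SD, n = 6) in Male KO. Mitochondrially encoded genes took 12.1% ± 2.7 of counts in Female WT, 12.6% ± 2.1 in Female KO, 8.54% ± 0.49 in Male WT and 10.3% ± 3.3 in Male KO. Among the male libraries Male KO replicate 3 had the highest share, 16.1%, and among the female ones Female WT replicate 5 reached 16.2%. The most abundant nuclear transcripts were Alb, Apoa2 and Apoe, which encode albumin and apolipoproteins, at 3.69%, 2.80% and 2.62% of counts on average. Principal components were computed from the most variable genes only. The leading principal component held 56% of the variance of those genes and separated the sexes. The next held 9.6% and was carried mainly by the shallow Male KO replicate 3, at -38.5 against -12.1 to 13.5 for all other libraries. On it Male KO replicates 1 and 2 lay at 8.9 and 6.36, and replicates 4, 5 and 6 at -5.31, -5.42 and -7.64.

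Cyp2e1 (ENSMUSG00000025479, chromosome 7) was far lower in every knockout library than in any WT library. In females its level was 398 ± 63.4 CPM (SD, n = 5) in WT and 26.3 ± 7.29 CPM (SD, n = 6) in KO, a 14.9-fold difference. In males it was 476 ± 54.0 CPM (SD, n = 6) in WT and 32.4 ± 13.1 CPM (SD, n = 6) in KO, a 14.3-fold difference. The log2 fold change was -3.89 (SE 0.21, adjusted p = 1.61e-12 by edgeR) in females and -3.84 (SE 0.21, adjusted p = 1.66e-12 by edgeR) in males. The highest knockout library reached 49.4 CPM and the lowest WT library 323 CPM. Cyp2e1 counts remained in all knockout libraries, at 6.56% of the WT level in females (95% counting interval 6.09% to 7.05%) and 6.73% in males (6.26% to 7.21%). The labels do not say which part of the gene is disrupted, and a 3' tag can lie outside it, so these values check the labels only through the difference between the groups.

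**Figure D1:**
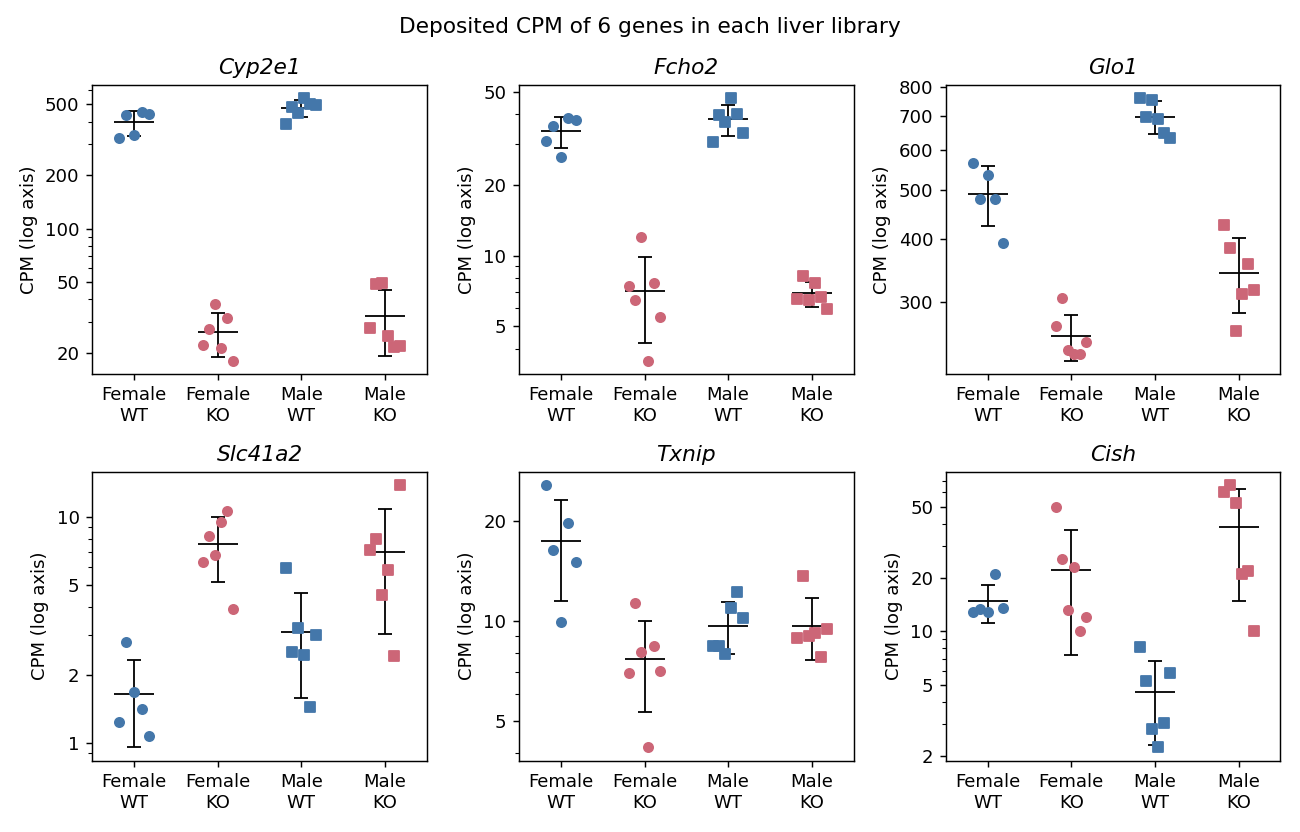
Deposited CPM on a log axis of Cyp2e1, Fcho2, Glo1, Slc41a2, Txnip and Cish in each of the 23 liver libraries, with points for libraries (circles for females, squares for males, blue for WT, red for KO), and a long bar and whiskers for the group mean ± SD. Cyp2e1, Fcho2 and Glo1 lay lower in all knockout libraries than in all WT libraries of the same sex, Slc41a2 lay higher in all Female KO than in all Female WT libraries, and Cish lay higher in all Male KO than in all Male WT libraries.

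Female livers of the knockout line had lower Fcho2, Glo1 and Txnip and higher Slc41a2 and Sult2a1 than those of the WT line. Fcho2 (ENSMUSG00000041685), which encodes a protein of early clathrin-coated pits, fell 4.70-fold, from 33.8 ± 5.18 CPM in WT (SD, n = 5) to 7.09 ± 2.82 CPM in KO (SD, n = 6), with adjusted p = 2.06e-09 by edgeR. Glo1 (ENSMUSG00000024026), which encodes the glyoxalase that acts first on methylglyoxal, fell 1.87-fold, from 491 ± 66.5 CPM to 256 ± 27.0 CPM, with adjusted p = 9.89e-06 by edgeR. Slc41a2, a magnesium transporter gene, rose 4.67-fold from 1.64 ± 0.684 CPM to 7.55 ± 2.41 CPM, with adjusted p = 0.00419 by edgeR. The hydroxysteroid sulfotransferase gene Sult2a1 rose 2.47-fold (adjusted p = 0.0207 by edgeR), with overlapping libraries.

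Of 11370 tested genes, edgeR called 22 in females, 9 higher and 13 lower in KO, and 1005 genes had an unadjusted p under 0.05 where 568 are expected by chance. Other genes named by the rule were Pear1 (log2 fold change -0.91), Plekhf1 (-0.74), the snoRNP core gene Nop58 (0.73) and the signal recognition particle genes Srp54a (0.79), Srp54b (0.71) and Srp54c (0.73). The Srp54 copies and Glo1 with its processed pseudogene Glo1-ps (-0.92) are near-identical and can share reads, so their separate values are uncertain. Chosen after their values were seen, Txnip (-1.14), Jarid2 (-0.96), P4ha2 (-0.83), Mir22hg (-1.33), Trmt12 (1.15) and Spryd4 (0.51) were also called, and 3 called genes were predicted or clone models. The calls of Fcho2, Glo1, Glo1-ps, Slc41a2, Txnip, Mir22hg and the Srp54 genes held in all 11 fits without 1 of the female libraries. Of these 11 fits, the call of Pear1 held in 9, Jarid2 in 8 and Sult2a1 in only 5. Those of Trmt12 and Spryd4 held in 4 each, Nop58 and Plekhf1 in 3 each and P4ha2 in 2. The count of called genes was 13 without Female WT replicate 1, 62 with no filter, 49 by limma-voom with sample weights, 47 by DESeq2 and 5 in a test against a log2 fold change of 0.5. With only the female groups in the fit it was 17, and 11 of these were among the 22.

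Among the gene lists in females, camera with the preset correlation ranked interferon response genes above and sinusoidal endothelium markers below other genes in KO, and with an estimated correlation neither was called. Of 33 interferon response genes, 28 had a positive fold change, with a median log2 fold change of 0.40. Adjusted over the list alone, 9 passed and all were higher, and over all genes tested 0 passed. Usp18 (0.99), Isg15 (0.98), Psmb9 (0.79) and Tap1 (0.58) were among these 9. The camera test gave adjusted p = 1.56e-08, and adjusted p = 0.253 with an estimated correlation. Of 14 sinusoidal endothelium markers, 13 had a negative fold change, with a median of -0.52. Adjusted over the list alone, 9 passed, among them Gpr182 (-0.69) and Clec4g (-0.68). The camera test gave adjusted p = 1.23e-10, and adjusted p = 0.253 with an estimated correlation. All 10 tested proliferation genes had a positive fold change, with a median of 0.64, and the replication licensing genes Mcm2 (1.20) and Mcm6 (1.25) passed when adjusted over the list alone. Their camera test gave adjusted p = 2.42e-04, and adjusted p = 0.187 with an estimated correlation.

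The other lists called in females moved less. Acute phase genes had a median of 0.24 (camera adjusted p = 8.35e-05; adjusted p = 0.641 with an estimated correlation), and antigen presentation genes 0.26 (camera adjusted p = 0.00165; adjusted p = 0.559 with an estimated correlation). NRF2 targets had a median of -0.17 (camera adjusted p = 0.00549; adjusted p = 0.493 with an estimated correlation), and targets of the xenobiotic receptors CAR and PXR -0.14 (camera adjusted p = 0.039; adjusted p = 0.559 with an estimated correlation). Fatty acid synthesis genes had a median of -0.11 (camera adjusted p = 0.0226; adjusted p = 0.778 with an estimated correlation), circadian clock genes -0.16 (camera adjusted p = 0.041; adjusted p = 0.659 with an estimated correlation) and immediate early genes -0.32 (camera adjusted p = 0.0226; adjusted p = 0.645 with an estimated correlation). With each female library left out in turn, circadian clock genes were called in only 4 of 11 fits (highest camera adjusted p = 0.155), CAR and PXR targets in 6, immediate early genes in 8, fatty acid synthesis in 9 and antigen presentation in 10. In all, camera called 10 of 35 lists in females with the preset correlation, 0 with an estimated correlation, and fry called 0, or 2 when members may move in either direction. Some lists that camera did not call hold called genes, such as Glo1 in ethanol, acetone and ketone metabolism and Sult2a1 in phase II conjugation. Camera left the remaining 25 lists uncalled. Among them were the cytochrome P450s other than Cyp2e1 (62 tested, median -0.00, camera adjusted p = 0.19), phase II conjugation (56 tested, median 0.02, adjusted p = 0.21), PPARA targets (37 tested, median 0.01, adjusted p = 0.539), ethanol, acetone and ketone metabolism (19 tested, median -0.02, adjusted p = 0.262), and pericentral hepatocyte genes (24 tested, median -0.05, adjusted p = 0.21).

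Male livers of the knockout line had higher Cish and, like the females, lower Fcho2 and Glo1. Cish (ENSMUSG00000032578), a cytokine signalling inhibitor that STAT5 induces, rose 8.83-fold, from 4.56 ± 2.28 CPM in WT (SD, n = 6) to 38.6 ± 23.9 CPM in KO (SD, n = 6), with adjusted p = 1.33e-04 by edgeR. Its log2 CPM after TMM scaling was 5.92, 5.94 and 5.98 in Male KO replicates 1, 2 and 3. It was lower, at 4.54, 4.70 and 3.54, in Male KO replicates 4, 5 and 6. Fcho2 fell 5.23-fold, from 38.0 ± 5.72 CPM to 6.91 ± 0.845 CPM, with adjusted p = 4.57e-10 by edgeR. Glo1 fell 1.93-fold, from 698 ± 52.7 CPM to 343 ± 58.3 CPM, with adjusted p = 1.75e-06 by edgeR. The immunoglobulin kappa constant gene Igkc (log2 fold change 1.44) and the forkhead factor gene Foxq1 (1.20) also rose (adjusted p = 0.0414 by edgeR for both).

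In males edgeR called 15 genes, 7 higher and 8 lower in KO, and 1492 genes had an unadjusted p under 0.05 where 568 are expected by chance. The rule also named Phlda1 (1.19), Kbtbd3 (0.96) and Glo1-ps (-0.86), and 2 called genes were predicted models. Chosen after their values were seen, Ccdc50 (0.78), the drug efflux pump gene Abcb1b (1.30), Ildr2 (-0.85) and Snai2 (-1.53) were also called. Only Cyp2e1, Cish, Fcho2, Glo1, Glo1-ps and the predicted models held in all 12 fits without 1 of the male libraries. The count was 7 without Male WT replicate 3, 4, 5 or 6, 9 without Male KO replicate 3 and 49 without Male KO replicate 2. It was 157 with no filter, 47 by DESeq2, 8 by limma-voom and 685 by limma-voom with sample weights, which gave Male KO replicates 1, 2 and 3 weights of 0.496, 0.318 and 0.51, and 6 in a test against a log2 fold change of 0.5. With only the male groups in the fit it was again 15, and 11 of these were among the main calls.

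Among the gene lists in males, camera with the preset correlation ranked interferon response, antigen presentation, Kupffer cell and female-biased genes above and male-biased and clock genes below other genes in KO. With an estimated correlation none of these was called, and 0 of their members passed over all genes tested. Interferon response genes had a median of 0.37, with 32 of 33 positive and 4 higher when adjusted over the list alone, among them Irf7 (0.53) and Ifi27 (0.75). Their camera test gave adjusted p = 9.99e-06, and adjusted p = 0.419 with an estimated correlation. The interferon response and antigen presentation lists both hold Psmb8, Psmb9 and Tap1, so in neither sex are they fully separate. Antigen presentation genes had a median of 0.49, with 17 of 19 positive and 10 higher when adjusted over the list alone, among them H2-Q7 (0.94) and H2-D1 (0.32). Their camera test gave adjusted p = 4.60e-05, and adjusted p = 0.419 with an estimated correlation. All 12 Kupffer cell and macrophage markers were positive, with a median of 0.61 (camera adjusted p = 0.00189; adjusted p = 0.516 with an estimated correlation). Stellate cell and fibroblast markers had a median of 0.35 (camera adjusted p = 0.0236; adjusted p = 0.493 with an estimated correlation). Of 34 female-biased liver genes, 28 were positive, with a median of 0.52 (camera adjusted p = 0.00422; adjusted p = 0.419 with an estimated correlation), and Abcd2 (1.48), Hao2 (3.69) and Cyp4a14 (2.95) passed when adjusted over the list alone. Several members were near or under the counting floor in males, so their signs and fold changes rest on few reads. Hao2 was at 0.0557 CPM in Male WT and 0.969 CPM in Male KO, and Sult3a2 at 0.0379 and 0.282 CPM. The rise of Cyp4a14 in Male KO had a 95% interval from -42.1% to 121% of its Female WT level. Of 29 male-biased liver genes, 18 were negative, with a median of -0.21 (camera adjusted p = 0.00528; adjusted p = 0.472 with an estimated correlation), and Cyp4a12b (-1.05), Cyp4a12a (-0.69), C6 (-0.64) and Cyp2d9 (-0.53) passed when adjusted over the list alone.

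Further lists called in males were the circadian clock with a median of -0.47 (camera adjusted p = 0.00281; adjusted p = 0.419 with an estimated correlation), acute phase with 0.27 (camera adjusted p = 0.00196; adjusted p = 0.516 with an estimated correlation) and NRF2 targets with -0.16 (camera adjusted p = 5.63e-04; adjusted p = 0.419 with an estimated correlation). CAR and PXR targets had a median of -0.12 (camera adjusted p = 0.0242; adjusted p = 0.419 with an estimated correlation), fatty acid synthesis -0.19 (camera adjusted p = 0.00281; adjusted p = 0.516 with an estimated correlation) and gluconeogenesis and glucose handling -0.13 (camera adjusted p = 0.00282; adjusted p = 0.419 with an estimated correlation). Gsta2 (-0.94), a glutathione transferase gene that is in both the NRF2 and the CAR and PXR lists, and Foxo1 (-0.85) in the glucose list passed when adjusted over their list alone. Camera called 12 of 35 lists in males with the preset correlation, 0 with an estimated correlation, and fry called 0, or 9 when members may move in either direction. Camera did not call the other cytochrome P450s (median -0.02, camera adjusted p = 0.559) or PPARA targets (0.02, camera adjusted p = 0.675). Nor did it call ethanol, acetone and ketone metabolism (-0.05, camera adjusted p = 0.15), a list that holds the called gene Glo1. A median near 0 can hide members that move in opposite directions. With each male library left out in turn, CAR and PXR targets were called in 8 of 12 fits, stellate cell markers in 9, male-biased genes in 10, and acute phase and fatty acid synthesis in 11. The highest camera adjusted p was 0.138 for acute phase without Male KO replicate 6, 0.0594 for fatty acid synthesis without replicate 3, and 0.119 for CAR and PXR targets, 0.0903 for male-biased genes and 0.0963 for stellate cell markers without replicate 2.

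**Figure D2:**
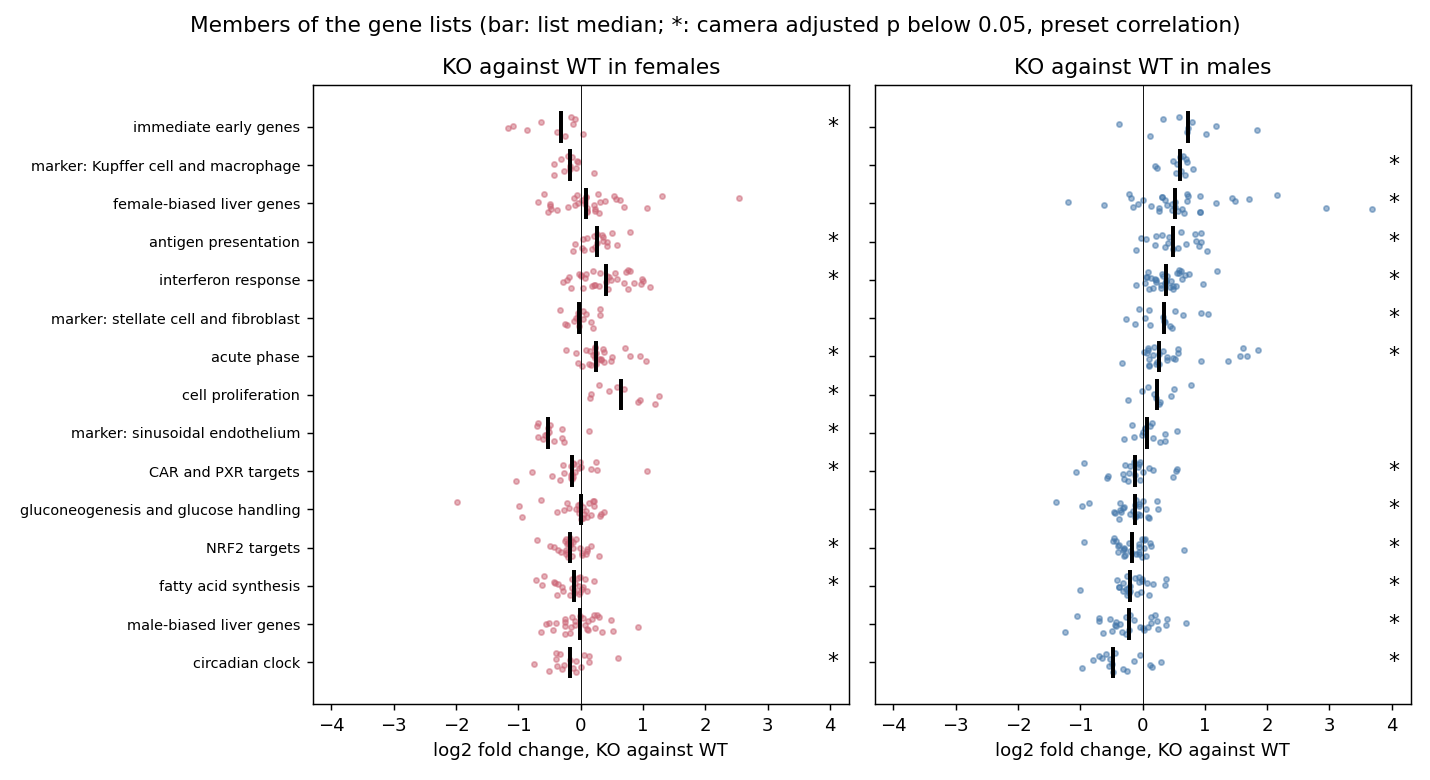
Log2 fold change of KO against WT for each tested member of the 15 gene lists called in either sex, with females on the left, males on the right, points for genes, a black bar for the list median and an asterisk for a camera adjusted p below 0.05 with the preset correlation. Interferon response members lie mostly to the right in both sexes, with medians of 0.40 and 0.37, and with an estimated correlation 0 lists were called in either sex.

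Genotype differences of the sexes overlapped in 6 genes, all lower in knockout livers of both. These were Cyp2e1, Fcho2, Glo1, Glo1-ps and, chosen after their values were seen, the lncRNA genes Gm10503 and Gm50252. By chance 0.00915 genes lower in both would be expected from independent lists. The 6 include the disrupted gene itself, and Glo1-ps can share reads with Glo1, so not all 6 are separate agreements. Gm10503 was at 10.2 ± 2.19 CPM in Female WT (SD, n = 5) and had 2 counts in all Female KO libraries together, 0.701% of the WT level (95% counting interval 0.0849% to 2.53%). It had 0 counts in the 6 Male KO libraries against 305 in Male WT, at least 71.1-fold lower with a floor of 3 counts over the group. Gm50252 remained at 2.93% of the WT level in females and 3.08% in males. At an unadjusted p under 0.05 in both sexes, 78 genes were higher in both, 81 lower in both and 15 opposite, against 40.9 and 25.4 expected from independent lists. Across all 11370 genes, which are not independent replicates, the log2 fold changes of the sexes had Pearson's r of 0.315 and Spearman's rho of 0.284, and 61.9% shared a sign.

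**Figure D3:**
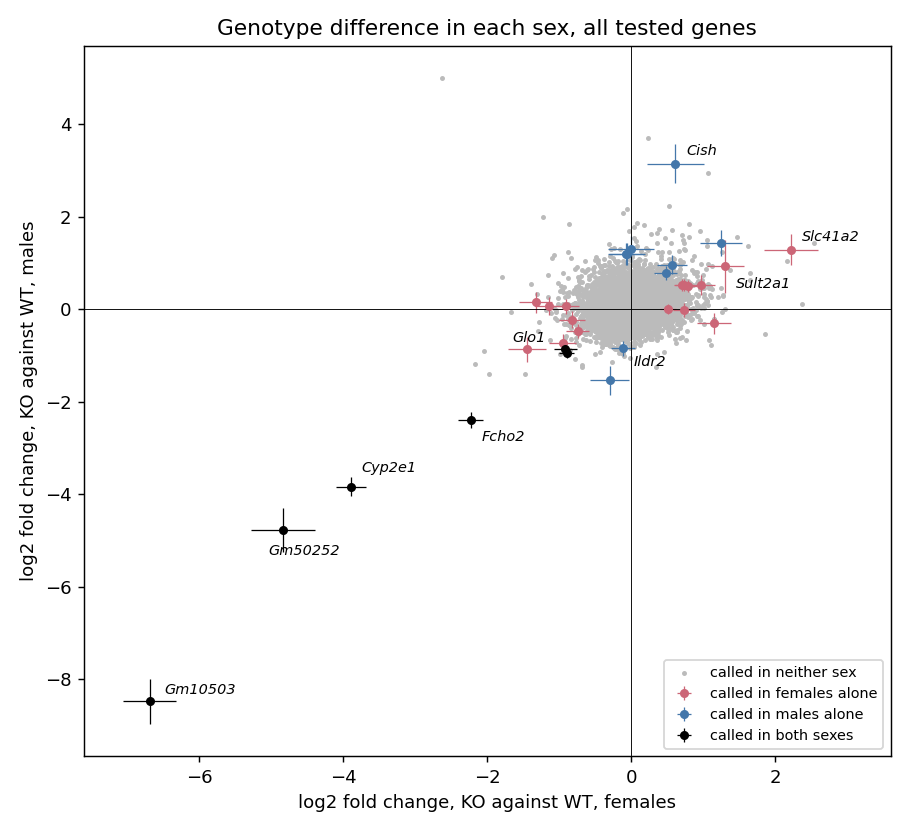
Fitted log2 fold change of KO against WT in females (horizontal) and males (vertical) for all 11370 tested genes, grey where not called, red where called in females alone, blue in males alone, black in both, with bars for ± 1 SE of called genes. The 6 genes called in both sexes lie at the lower left, and the fitted value of Gm10503 in males, where knockout libraries held 0 counts, depends on the prior count and is no bound.

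The disrupted gene could sit in a segment of another line, so called genes were counted near it. Within 20 Mb of Cyp2e1 on chromosome 7, edgeR called 0 of 209 tested genes in females and 0 in males besides Cyp2e1 itself, while 16 and 21 had an unadjusted p under 0.05. Only 0.395 and 0.263 calls would be expected there, so a count of 0 and Fisher's exact test (2-sided, p = 1 in both sexes, also within 10 Mb and 40 Mb) decide little. The share of genes with an unadjusted p under 0.05 was 7.66% inside against 8.87% outside in females and 10.1% against 13.2% in males. In each sex 1 pair of called genes stood next to each other among tested genes, Glo1 and Gm50252 on chromosome 17. Shuffled positions gave as many pairs with p = 0.044 in females and 0.019 in males over 1000 shuffles (permutation test, adjusted 0.044 and 0.038 over both).

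The test of whether the genotype difference depended on sex, the interaction, called 0 genes by edgeR. The smallest adjusted p was 0.409, and 643 genes had an unadjusted p under 0.05 where 568 are expected. DESeq2 and limma-voom with and without weights also called 0, while the fit with no filter called 25. A gene called in only 1 sex, such as Cish or Txnip, is therefore not shown to differ between the sexes. At the level of lists, camera called 5. Immediate early genes (median of male minus female difference 1.04, camera adjusted p = 0.00141), Kupffer cell markers (0.80, camera adjusted p = 8.97e-06), sinusoidal endothelium markers (0.56, camera adjusted p = 3.62e-08) and stellate cell markers (0.35, camera adjusted p = 0.0318) ranked above other genes, and amino acid and urea cycle genes below them (-0.13, camera adjusted p = 0.0043). All 5 had adjusted p = 0.784 with an estimated correlation, and fry called 0. Without Male KO replicate 2 camera called 2 lists, without Male KO replicate 3 it called 3, and without other libraries up to 9.

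Male and female livers differed far more than the genotypes did. In WT, edgeR called 638 genes, 268 higher and 370 lower in males, and in KO 846, with 417 higher and 429 lower. Of these, 415 were called in both genotypes with the same sign and 0 with opposite signs. Whether the others differ by genotype is the interaction tested above. The sulfotransferase genes Sult3a1, Sult3a2, Sult2a5 and Sult2a2 were among the 5 genes most strongly female-biased in each genotype, with Hao2 (-7.86) in WT and Sult2a1 (-7.98) in KO. Sult3a1 was at 497 ± 101 CPM in Female WT (SD, n = 5) and 1.42 ± 0.727 CPM in Male WT (SD, n = 6), with a log2 fold change of -8.40 and adjusted p = 3.22e-18 by edgeR. The fatty acid hydroxylase gene Cyp4a12a had the largest male bias, at 704 ± 76.2 CPM in Male WT and 2.51 ± 0.947 CPM in Female WT, with a log2 fold change of 8.20 and adjusted p = 7.38e-19 by edgeR. The major urinary protein genes Mup7 (7.52 in WT, 7.36 in KO) and Mup15 (7.59 in WT, 7.42 in KO) and the pairs Sult3a1 with Sult3a2 and Cyp4a12a with Cyp4a12b have near-identical copies that can share reads, so their separate values are uncertain. Hsd3b5 (8.07 in WT, 7.24 in KO), Cyp4a12b in WT (7.30) and Obp2a in KO (6.92) completed the named male genes.

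The sex chromosome genes matched the labels in every library. Xist was at 158 ± 56.4 CPM in Female WT (SD, n = 5), 115 ± 38.7 in Female KO (SD, n = 6), 1.64 ± 0.987 in Male WT (SD, n = 6) and 3.00 ± 0.913 in Male KO (SD, n = 6). The Y-linked gene Ddx3y was at 45.3 ± 4.19 CPM in Male WT and 0.537 ± 0.457 CPM in Female WT, and Eif2s3y, Uty and Kdm5d were likewise higher in males of both genotypes. Male-biased genes had a median of 3.61 in WT and 3.59 in KO, and female-biased genes -5.00 and -4.43. With an estimated correlation their adjusted p was 5.59e-08 and 2.49e-08 in WT and 7.40e-07 and 3.51e-07 in KO. Of the lists, camera called 11 in WT and 12 in KO, of which 3 and 4 kept an adjusted p under 0.05 with an estimated correlation. In KO the count of called genes was 1693 without Male KO replicate 2, 1572 without Female KO replicate 4, 398 with only the KO groups in the fit and 248 in a test against a log2 fold change of 0.5. In WT it was 1121 with only the WT groups and 247 against a log2 fold change of 0.5, and with sample weights limma-voom called 1250 in WT and 2091 in KO.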

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

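Of the tests below, those on a segment next to Cyp2e1, on Glo1 and Glo1-ps, on the chromosome 17 stretch, on carry-over or WT tissue, on swapped labels, on divided reads and on female RNA were chosen only after the result was seen. Those on the shallow library, on growth hormone and on the random splits were chosen before.

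Single libraries lay apart from the others of their group in 10 of 88 groups of values, where chance alone gives about 1 in 20. In Female KO replicate 3, Nop58 was 38.4 CPM (others 21.0 to 24.2) and Glo1-ps 5.94 CPM (3.34 to 4.12). Sult2a1 was 293 CPM in Female WT replicate 4 (116 to 157) and Srp54c 6.92 CPM in Female WT replicate 3 (5.78 to 5.97). In Male KO replicate 2, Abcb1b was 13.0 CPM (2.41 to 5.16), Gm50252 0.459 CPM (0 to 0.121) and counts outside the table made up 0.927% (0.605% to 0.723%). Ildr2 was 26.8 CPM in Male WT replicate 2 (42.2 to 50.1). Library totals were 5333015 in Female KO replicate 6 (4314392 to 4658677) and 9874733 in Male WT replicate 3 (4366909 to 5940507). The cause of these values was not tested. In the interaction, the list medians of amino acid and urea cycle (-0.13), immediate early (1.04), Kupffer cell (0.80), sinusoidal endothelium (0.56) and stellate cell genes (0.35) ranked apart from other genes by camera with the preset correlation, with adjusted p = 0.784 for all 5 with an estimated correlation and 0 lists called by fry.

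Of the 6 genes called in both sexes, Glo1, Gm50252 and Gm10503 start within 1 Mb of each other on chromosome 17. The tested neighbours of Glo1 examined there, Btbd9, Gm6402, Gm8373 and Abcg1, were not called. Btbd9 was lower in KO of both sexes (-0.34, unadjusted p = 0.0507 by edgeR in females, and -0.62, 7.79e-04 in males). Gm6402 went the other way (0.26, unadjusted p = 0.295 by edgeR in females, and 0.65, 0.0153 in males). Gm8373 was also positive (0.03 in females and 0.32 in males), and Abcg1 differed in sign (-0.26 and 0.16). A segment kept next to the disrupted gene would place these genes on chromosome 7, and 0 of the 5 besides Cyp2e1 lie there. The Glo1-ps and Glo1 log2 fold changes differ by at most 0.491 combined SE, so reads of Glo1 assigned to its pseudogene could account for the Glo1-ps call. None of 10000 random draws of 6 tested genes held 3 within 1 Mb (permutation p = 1e-04, the smallest these draws can give), but that window was set after the positions were seen, so the p describes this arrangement only. A difference between the lines in that stretch and an effect of the Cyp2e1 disruption cannot be told apart, because each genotype is 1 line.

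Cyp2e1 counts stayed at 6.56% of the WT level in Female KO and 6.73% in Male KO. Carry-over between libraries or a share of WT tissue would leave other transcripts at the same share, but Gm10503, chosen after its drop was seen, stayed at 0.701% in females with an upper limit of 2.53%, while Gm50252, at 2.93% (0.799% to 7.51%) in females and 3.08% (0.636% to 9.02%) in males, is too sparse to decide. A swapped label would give a library near the WT level, and the highest KO library held 15.3% of the lowest WT library. Reads divided between Cyp2e1 and another gene might contribute, since 10 of 12 KO libraries had a Cyp2e1 count that was not whole, but 8.8% of 3249 genes with like counts had as many, a second criterion set after the first outcome, so this leaves it open. A transcript from a part of the gene outside the disruption was not tested, because the table has no read positions.

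Female-biased genes ranked above other genes in Male KO against Male WT by camera with the preset correlation, with a median of 0.52 (adjusted p = 0.419 with an estimated correlation), and without the shallow Male KO replicate 3 the median stayed at 0.51. Female RNA in Male KO libraries would lift each member by about the share by which Xist rose, 0.861% of the female level (95% interval 0.256% to 1.47%). The median rise of all 34 members was 0.264% (0.015% to 0.514%, with the Male WT mean held fixed), but members ranged from -23.3% (Ntrk2) to 39.6% (Cyp4a14). Of the members, 29 had an interval that overlapped that of Xist, 4 lay below it, among them Sult3a1 (0.0746%), and 1 above it. Sult2a6, also among the 4, was at 2.84 CPM in Female WT and 0 CPM in both male groups, too sparse to decide. Overlap can come from a wide interval alone, such as -13.1% to 20.8% for Acot3. The tally therefore leaves female RNA open. Earlier versions parted the list by male level, first at 2% by mistake and then at the 5% set beforehand, and were dropped because the level under test decided the parts. A growth hormone change might link Cish to this list, but over the 6 Male KO libraries r was 0.16 (exact permutation p = 0.715), Spearman's rho 0.371 (p = 0.497), and r without the 2 farthest libraries -0.778, which leaves it open.

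Group labels were exchanged at random in 100 of the possible splits, and the edgeR count was taken for each. The KO against WT count in females was 22, with a highest other split of 5 and 1 split as large counting the real one. In males it was 15, with a highest other of 45 and 2 as large. That share is under 0.05, but it concerns the count as a whole, which includes Cyp2e1, and not any single call. A split with several times the real count may point to a structure of the samples, and such splits were not examined further. For the interaction the count was 0, so all 100 splits are as large whatever the data hold and that number decides nothing. The highest other split there, with 389, may likewise point to a structure of the samples. For sex the count was 638 in WT, with a highest other of 317 and 1 as large, and 846 in KO, with a highest other of 2112 and 2 as large. Every other split for sex mixes male and female libraries. A high count there cannot be told apart from the sex difference itself and shows no further structure. By limma-voom with sample weights the male count was 685, with a highest other of 644 and 1 as large.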

How the results depend on the processing

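The limits of the counts lie in the filter, the tool, the groups in the fit and single libraries. KO against WT in females gave 22 called genes, 62 with no filter, 5 against a log2 fold change of 0.5, 49 by limma-voom with sample weights, 47 by DESeq2, and 13 to 24 when each library was left out. In males the 15 became 157 with no filter, 6 against 0.5, 685 by limma-voom with sample weights, 8 without weights, 47 by DESeq2, and 7 to 49 with 1 library left out. The interaction stayed at 0 in all of these but no filter, with 25. With only the compared groups in the fit, 17 genes were called in females, 11 of them among the 22. In males that fit called 15, 11 of them among the main 15. With no filter, 16 of the 22 and 14 of the 15 were called again. A like count thus does not mean the same genes. For sex in WT, 638 became 247 against 0.5, 1121 with only the WT groups, 1250 with sample weights, and 502 to 566 with 1 library left out. For sex in KO, 846 became 248 against 0.5, 398 with only the KO groups, 2091 with sample weights, and 592 to 1693 with 1 library left out. The overlap of 6 genes became 14 at an unadjusted p in males, 159 at an unadjusted p in both, 12 by DESeq2 and 16 with sample weights. Lists called by camera were 10 in females, 12 in males and 5 in the interaction, 0 each with an estimated correlation or by fry, and 7 to 15, 9 to 16 and 2 to 9 with 1 library left out. For sex the 11 lists in WT became 3 and the 12 in KO 4 with an estimated correlation, and 9 to 14 and 5 to 17 with 1 library left out. With 1 library left out Cyp2e1 lay between -4.00 and -3.81 in females and -4.01 and -3.77 in males, and with sample weights at -4.07 in males. With a replicate block the counts were 15, 12, 1, 595 and 844, and the numbers were not taken as pairs, because not every same-numbered pair had a correlation over 0.1 (2 of 5, 2 of 6, and across the sexes 3 of 5 in WT and 3 of 6 in KO). Across the sexes the mean same-number r was 0.157 in WT and 0.142 in KO, against 0 and 0.001 over all pairs, so a shared factor stays open there; 1, 0, 1 and 2 libraries correlated best with their own number. The cause of these shifts was not tested.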

Other observations

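The genotype difference averaged over both sexes was added after the data were seen, and the genes named here were chosen after their values were seen. Averaged, KO livers had higher immunoglobulin transcripts Igkc (log2 fold change 1.34, SE 0.21) and Igha (1.51, SE 0.25, adjusted p = 0.00197 by edgeR), and lower Lpin2 (-0.87, adjusted p = 9.93e-04 by edgeR), Ppara (-0.63, adjusted p = 0.0351 by edgeR) and Irs2 (-0.98, adjusted p = 0.0203 by edgeR). The interferon response genes Psmb9 (0.70, adjusted p = 0.0351 by edgeR), Isg15 (0.81, adjusted p = 0.0366) and Usp18 (0.73, adjusted p = 0.0417) were higher. In all 49 genes were called, 22 higher and 27 lower, and 30 of them in neither sex alone. Without the shallow Male KO replicate 3, 45 were called and 41 shared, and Isg15 (adjusted p = 0.0582) and Usp18 (adjusted p = 0.066) were lost.

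Transcripts far higher in 1 sex had small values in the other. Xist in Male WT stood at 1.03% of the Female WT level and in Male KO at 2.61% of Female KO. Ddx3y in females stood at 1.19% of the male level in WT and 1.26% in KO. Sult3a1 in males was at 0.286% and 0.369%, and Mup7 in females at 0.581% and 0.687%. The cause was not tested.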
